A study of Danio rerio with 3 samples.

How the data were processed

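RNA was compared between zebrafish (Danio rerio) embryos injected with MO-grnA and untreated wild-type embryos, both at 22 hours post fertilization (hpf). MO-grnA is a morpholino, an antisense oligomer, directed at granulin A, and per the labels' protocols 2 to 3 nl was injected at the 1-cell stage. Each of 3 biological replicates took 200 embryos per group. Total RNA was extracted with Trizol, and 1 µg was amplified and labelled with cyanine dyes by the Agilent Quick Amp kit, per the labels' protocols. Every array held morphant RNA in 1 channel and wild-type RNA in the other. Morphant RNA carried Cy5 in replicates 1 and 2 and Cy3 in replicate 3, the dye swap, per the labels.

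The arrays were of Agilent design 019161 and were quantified by the authors with Agilent Feature Extraction. The submitters' processing notes name version 8.5.1.1 and the file headers name version 10.5.1.1. The deposited files give for each spot the median pixel intensity of both dyes, the local background intensity, background-subtracted and dye-normalized processed intensities, and a log10 ratio of red over green, per the file headers. The series' value table was compared with these columns spot by spot. Its log10 values were the deposited log ratios, with the sign of replicate 3 turned (largest difference 4.95e-06), so their scale is log10, and each column's median was 0. Which dye held morphant RNA, and with it the direction of every ratio, rests on the dyes in the labels.

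All values reported here were recomputed from the median intensities. The design fixed before the data were examined named mean intensities, which these compact files do not hold, so median intensities were used. Background was corrected with normexp at an offset of 50 and ratios were loess-normalized within each array in limma 3.58.1 under R 4.3.3. Control spots and spots marked as non-uniform or as population outliers had weight 0. The ratio of replicate 3 was multiplied by -1, so that every log2 ratio is morphant over wild type. Spots of a probe were averaged. An offset of 50 pulls the ratios of dim probes toward 0.

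Each array held 45220 spots, 43803 of them not controls, and 43603 distinct probes. A probe was kept if it was well above background on all 3 arrays in the morphant channel or on all 3 in the wild-type channel, which 28688 probes were. Of these, 3622 lacked an unmarked spot on some array and were left out, leaving 25066 tested probes. No probe was saturated. On replicate 1, 7.49% of the spots that were not controls were marked, against 0.915% on replicate 2 and 0.909% on replicate 3. Replicate 1 was on slide 1 and replicates 2 and 3 shared slide 2, with the scans grouped the same way. Because each array is a morphant and wild-type pair, slide differences do not run along the groups.

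Probes were named from the accession in the files, without its version, through a RefSeq gene table of assembly GRCz12tu. The file headers name an older build, so no coordinates are given. In all, 16770 probes matched 11668 symbols and 26833 probes stayed unnamed. The tested probes covered 9227 named genes, 2677 of them with more than 1 tested probe. For genes, the probe with the highest mean intensity was used, and other probes of a gene are given in the text where their value differed clearly.

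The log2 ratio of each probe was tested against 0 with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The 3 arrays limit the precision and leave 2 residual degrees of freedom per probe before eBayes pools the spread over probes. Values are given as the log2 ratio with its moderated standard error (SE), n = 3 arrays. Below, "rose" and "fell" are used of genes past this threshold. A probe not well above background in any morphant channel is given as a bound, "at least N-fold lower". It sets the wild-type mean against the higher of the probe's own signal and the lowest signal among probes well above background, per channel after loess and Aquantile normalization, and remains open to dye bias because 2 arrays run against 1.

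The 45 gene lists were written before the data were examined, from textbook markers of embryonic tissues, signalling targets, stress responses and housekeeping complexes. Lists with at least 5 measured genes, 43 in all, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation was an alternative, and fry was run beside it. Fry asks whether a list's genes move on balance in a direction, or move at all, and does not compare the list with other genes. Several lists caught related genes through their name pattern, such as psmc3ip and psme3ip1 in the proteasome list and ndufaf assembly factors in the respiratory chain list.

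The genes named in the text follow a rule fixed before the data were examined. It takes every measured granulin family gene, the 12 largest rises and 12 largest falls among genes with a symbol that pass the threshold and move the same way on all 3 arrays, and up to 4 members of smallest adjusted p of each list described. It also takes any member a list is named for, the HGF and MET members that pass, and met itself.

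The pipeline was tested on simulated arrays with the real intensities, an added dye curve and 200 probes changed by known amounts among 28688 simulated probes. The simulated noise was drawn independently for each probe, so correlation between genes was not part of the test. Of the real probes 37.6% passed the threshold, a far larger share than was changed in the simulation. The adjusted threshold was therefore stricter in the simulation, and its shares of called probes do not carry over to the real arrays. For the comparison of morphant with wild type, 100% of simulated log2 changes of 2, 91.0% of changes of 1 and 13.6% of changes of 0.5 were called with the right sign. The median estimates were 1.78, 0.87 and 0.41. Among 28447 unchanged probes, 4 were called. A list given a shift of 0.3 was called by camera at the preset correlation (adjusted p = 1.0e-26), and no other list of the 43 was. With an estimated correlation the same known shift was not called (adjusted p = 0.591).

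Alternatives covered Agilent's own log ratio, the series' value table, no background correction, an offset of 16, median centring, scaling between arrays, other filters on dim probes, a dye term, marked spots kept, another prior, and leaving out each replicate. For the lists they also covered an estimated correlation and the mean of all probes of a gene. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. ENSDART, contig and expressed sequence tag accessions that the gene table does not hold were left unnamed, and control morpholino embryos were not analysed here. Some results, among them 1 of the called lists, are not reported here, and counts over all genes and lists include them.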

Results

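Transcript levels in embryos injected with MO-grnA, the morpholino directed at granulin A, were compared with those in wild-type embryos at 22 hpf. They were measured on 3 Agilent arrays with 2 colours each. Granulin A is a zebrafish relative of progranulin, a secreted growth factor that is also found in lysosomes. The comparison asks which transcripts differ in whole embryos after injection of the morpholino. Each array paired RNA of 200 injected embryos with RNA of 200 untreated embryos, and the arrays are biological replicates. The wild-type embryos were not injected, so any effect of injection itself is part of every ratio. Between 28635 and 31551 spots of an array were well above background in the morphant channel and between 28822 and 31010 in the wild-type channel. The median spot intensity of the morphant channel was 446.5 on replicate 1, 153 on replicate 2 and 114 on replicate 3. The wild-type medians were 191, 110.5 and 170.

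The morphant transcriptome differed widely from wild type, with mostly small changes and a set of very large ones. Of 25066 tested probes, 9435 (37.6%) passed the threshold, 4514 higher and 4921 lower in morphants. A change of at least 2-fold was seen for 971 probes, 416 higher and 555 lower, and at least 4-fold for 116, 59 higher and 57 lower. With Agilent's own log ratio, 2160 probes changed at least 2-fold. The median size of a called change was 0.46 on the log2 scale. Among 9227 named genes, 1780 rose and 2030 fell. The log2 ratios of the dye-swapped replicate 3, once turned, ran with those of the others across probes (r = 0.818 with replicate 1 and 0.851 with replicate 2, against 0.837 between replicates 1 and 2). Of the called probes, 9425 had the same sign on all 3 arrays. Within slide 2 alone, that is without replicate 1, 8233 probes passed, and slide 1 holds a single array and gives no test. Without replicate 3, the dye swap, the count was 6187, and with median centring in place of loess it was 715, with 409 higher and 306 lower, so that the larger share was higher and not lower. Of 182 called genes that the naming rule covers, 127 lost their call with median centring, and these are given one by one only for the granulin, partner, HGF and MET genes.

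Transcript of the targeted gene was not lower in morphants. The grna probe rose by 0.31 (SE 0.08, n = 3, 1.24-fold, adjusted p = 0.0227), higher on all 3 arrays, with 0.19 within slide 1 and 0.36 within slide 2. Its relative grnb rose by 0.58 (SE 0.13, 1.49-fold, adjusted p = 0.00867), while grna.2 had a log2 ratio of 0.07 (SE 0.08, adjusted p = 0.562). A morpholino can block translation without lowering the transcript, or alter splicing outside a probe, and its type is not given in the sources used here, so these probes do not check the labels. The grna call ended without replicate 2 (adjusted p = 0.107), without replicate 3 (adjusted p = 0.109) and with median centring (adjusted p = 0.424), at which the grnb call ended too (adjusted p = 0.277). Over all settings the adjusted p of grna lay between 0.00992 and 0.424. Among the measured partners of progranulin, psap, which encodes the lysosomal precursor prosaposin, rose by 0.64 (SE 0.09, adjusted p = 0.00125). The values for tnfrsf1a (-0.13, second probe 0.06), epha2a (-0.14) and the sortilin gene sort1a (0.01) did not pass.

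Genes of the HGF and MET pathway, a growth factor and its receptor tyrosine kinase with roles in liver growth, moved in both directions. Of 10 measured members, 1 rose, 3 fell and 6 did not pass, with the same counts adjusted over the list alone. Over all 9227 named genes 41.3% passed, so the called share of this list was close to that of all genes. The adaptor gene grb2b rose by 1.11 (SE 0.10, adjusted p = 1.6e-04). The gene for the HGF-related factor mst1 fell by 0.64 (SE 0.08, adjusted p = 8.4e-04). Smaller falls were measured for the receptor gene met, at -0.26 (SE 0.08, adjusted p = 0.0363), and for hgfa, at -0.27 (SE 0.09, adjusted p = 0.0419). These probes were dim, with mean log2 intensities of 7.08 (met) and 7.16 (hgfa) against 13.7 for mst1. The offset pulls dim ratios toward 0, so the sizes are not on an equal footing. The list as a whole was not called (adjusted p = 0.676, and 0.823 with an estimated correlation). The met call ended without replicate 2 (adjusted p = 0.144), without replicate 3 (adjusted p = 0.140), with a dye term (adjusted p = 0.0584) and with median centring (adjusted p = 0.560). That of hgfa ended with any replicate left out (adjusted p = 0.166, 0.105 and 0.0818 without replicates 1, 2 and 3), with a dye term (adjusted p = 0.0995) and with median centring (adjusted p = 0.709), where the mst1 and psap calls ended too (adjusted p = 0.481 and 0.222).

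**Figure D1:**
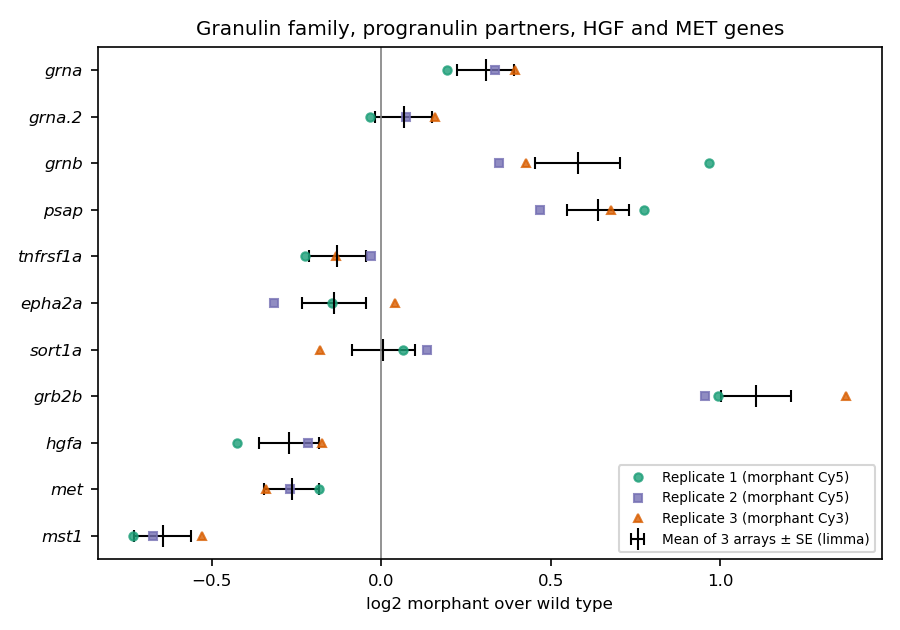
Log2 ratio of morphant over wild type (x axis) for granulin family genes, progranulin partners and called HGF and MET genes (y axis), with a point for each of the 3 arrays and the mean with its limma SE. The grna, grnb, psap and grb2b points lie above 0 on all 3 arrays, and the met, hgfa and mst1 points lie below 0.

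The largest rise was in rrm2b, a ribonucleotide reductase subunit, at 5.07 on the log2 scale (SE 0.13, 33.7-fold, adjusted p = 8.9e-07). Next came ctsba, which encodes the lysosomal protease cathepsin B, at 4.60 (SE 0.22, 24.3-fold, adjusted p = 8.5e-06), and the Integrator subunit gene ints14 at 3.91. The zinc finger gene znf1156 (3.41), lmbr1l (3.25), dcaf13 (3.07), the leukaemia inhibitory factor receptor gene lifra (3.01), cdc42se1 (3.01) and dap1b (2.98) followed. The 12 largest rises were completed by the hairy-related gene her12 (2.57), the transporter gene slc47a1 (2.54) and the ribosomal protein gene rpl36 (2.48). Second probes of lifra (2.49) and rpl36 (2.54) gave similar sizes. Moderated SEs over these 12 genes lay between 0.08 and 0.22. The standard deviation over the 3 arrays ran from 0.07 (lifra) to 0.71 (ctsba). For ctsba, replicate 1 gave 3.78, while replicates 2 and 3, on the other slide, gave 5.00 and 5.03.

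The largest fitted fall was in eef2a.1, a translation elongation factor gene, at -4.87 (SE 0.08, adjusted p = 2.0e-07). Its morphant signal was well above background on only 1 of 3 arrays, so the size is less certain than the SE shows, and a second probe gave -2.20. The oxygen sensor gene egln3 fell by 3.46 (SE 0.09, adjusted p = 8.9e-07) and the glycerol-3-phosphate dehydrogenase gene gpd1a by 3.15 (SE 0.08). The organizer homeobox gene gsc (goosecoid) dropped by 3.01 (SE 0.10) and hpdb, of tyrosine breakdown, by 2.91. Falls followed in the egg envelope genes zp3.1 (-2.68) and zp3f.1 (-2.56), cyp2aa7 (-2.68), ppt2a.4 (-2.48), the linker histone gene h1-10 (-2.37) and mpdu1b (-2.29). The morphant signal was well above background on 2 of 3 arrays for hpdb and cyp2aa7. For ppt2a.1 it was not well above background on any, and the mean over arrays was at least 4.54-fold lower in morphants (adjusted p = 2.1e-04). That bound is 2.18 on the log2 scale. The measured log2 ratio of ppt2a.1 was -3.22 on replicate 1. On replicates 2 and 3 the measured fall was smaller than the bound (-1.86 on replicate 3). The bound therefore describes the mean, to which replicate 1 adds most, and not each array. A second ppt2a.4 probe gave -0.88.

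**Figure D2:**
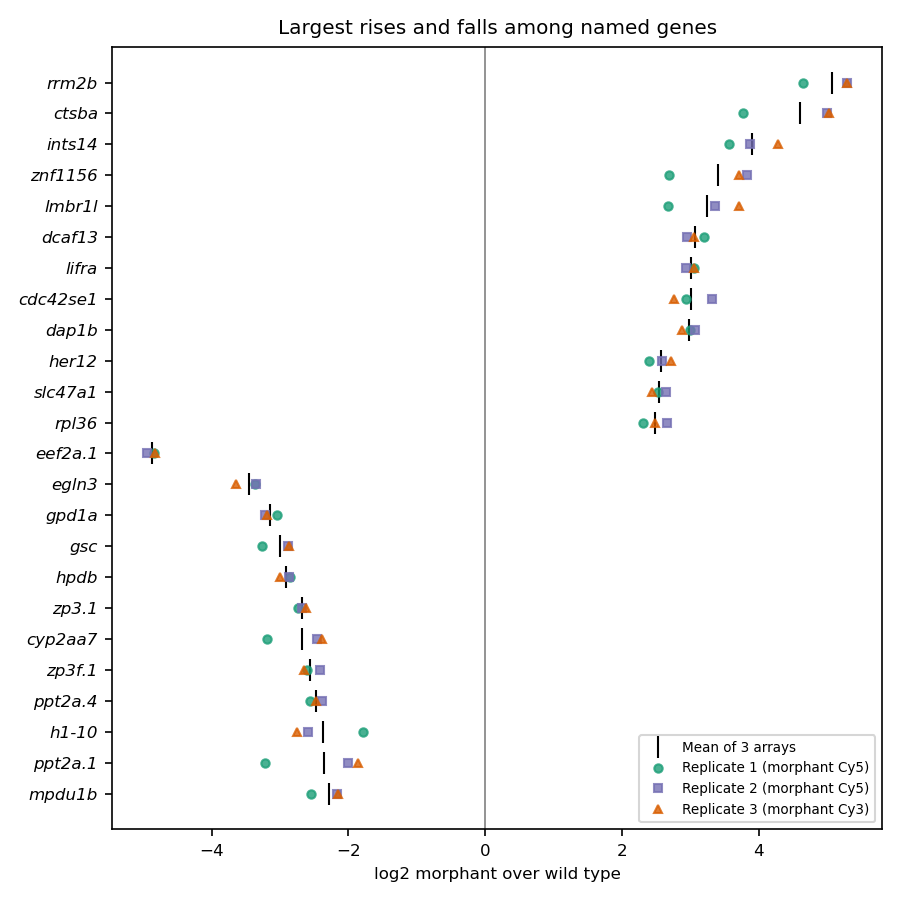
Log2 ratio of morphant over wild type (x axis) of the 12 largest rises and 12 largest falls among genes with a symbol (y axis), with a point per array and a bar at the mean. The means run from -4.87 for eef2a.1 to 5.07 for rrm2b, and the genes were chosen among those with the same sign on all 3 arrays.

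Of 43 tested gene lists, 15 were called with the preset correlation, 5 higher and 10 lower in morphants. None was called with an estimated correlation in limma's camera (smallest adjusted p = 0.497), where 1 list had an unadjusted p under 0.05. Fry's directional test passed 33 lists, all 15 of these among them, and its test in either direction passed all 43. Among the 15 called lists the estimated correlation ran from -0.04 (otic vesicle and lateral line) to 0.18 (germ plasm and maternal), against the preset 0.01. It was 0.17 for the ribosome, 0.11 for the respiratory chain and 0.07 for the proteasome. If these estimates hold, the preset makes the p of such lists too small. Under every alternative each of the 15 lists kept its direction. The medians of the lists that fell lay between -0.41 and -0.12 within slide 1 and between -0.37 and -0.20 within slide 2, and those of the lists that rose between 0.09 and 0.55 and between 0.14 and 0.29. In the simulation a list with a known shift was not called with an estimated correlation either. Its noise was independent between probes and only 1 list was shifted. For lists with an estimate above the preset, it therefore cannot tell lack of power from overstated preset calls. The estimate lay below the preset for the presomitic (-0.02), otic (-0.04), myogenic (-0.03) and ERK and FGF (-0.005) lists. Their unadjusted camera p rose all the same with the estimate. It went from 3.4e-06 to 0.0303, from 0.00364 to 0.0836, from 0.0123 to 0.108 and from 0.00870 to 0.101. If the estimates hold, these values argue against correlation between genes as the reason that these calls ended.

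Genes of the presomitic mesoderm and of somite segmentation were lower in morphants. Of 47 measured members, 29 fell, 6 rose and 12 did not pass (6 rose and 30 fell adjusted over the list alone), with a median log2 ratio of -0.37. The call had adjusted p = 7.3e-05, or adjusted p = 0.497 with an estimated correlation. The ventral homeobox gene ved fell by 1.91 (SE 0.09, adjusted p = 7.8e-06), and so did the caudal-related gene cdx1a (-1.66, SE 0.10) and wnt8a (-1.15, SE 0.08). Against the list, her12, a member of the Notch-regulated hairy family, was the member with the smallest p and rose by 2.57. A second cdx1a probe gave -0.33, while second probes of ved (-1.81) and wnt8a (-1.08) were close to the first. The list shares 20 of its measured genes with other lists. Among the lower lists described below, this number was 14 for otic vesicle and lateral line, 9 for endoderm and liver, and 8 for notochord and floor plate. It was 7 for pronephros, 7 for BMP and TGF beta, 6 for myogenic regulators, 4 for ERK and FGF, and 1 for germ plasm and maternal transcripts. Calls of lists that share genes are not independent.

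Genes that specify endoderm and liver were lower as well. Of 22 measured, 12 fell, 2 rose and 8 did not pass, with the same counts adjusted over the list alone and a median of -0.44. The adjusted p was 0.0115, or adjusted p = 0.497 with an estimated correlation. The early endoderm regulator sox32 fell by 1.87 (SE 0.08, adjusted p = 5.9e-06), with a second probe at -1.81, and sox9b fell as well (-1.92, SE 0.09). The genes mixl1 (-1.13) and gata5 (-1.06) fell too, and second probes gave -0.24 for mixl1 and -0.65 for gata5. By contrast, products secreted by hepatocytes and the yolk syncytial layer had 10 rises and 3 falls among 19 measured, unchanged when adjusted over the list alone. That list was not called (adjusted p = 0.0994, and 0.497 with an estimated correlation). The apolipoprotein genes apoa4a (0.74) and apoa4b.1 (0.80) rose, and the vitamin D binding protein gene gc (-2.24) and apoeb (-0.93) fell, with a second gc probe at -0.45.

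Targets and members of BMP and TGF beta signalling fell in 11 of 24 measured genes and rose in 2, with the same counts adjusted over the list alone. The median was -0.18 and the adjusted p was 0.0271, or adjusted p = 0.497 with an estimated correlation. The 4 members of smallest p all fell. They were the ventral homeobox genes ved (-1.91) and vent (-1.23, second probe -0.50), the BMP antagonist gene chrd (chordin, -1.17) and the Nodal antagonist gene lft1 (lefty, -1.16). In the list of ERK feedback and FGF targets, 11 of 23 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.19 and adjusted p = 0.0312, or adjusted p = 0.497 with an estimated correlation. Falls were measured for spred2b (-1.32), etv5b (-1.11), egr2b (-0.83) and the ligand gene fgf8a (-0.73). The ERK and FGF call ended without replicate 2 (adjusted p = 0.0555), without replicate 3 (adjusted p = 0.0536), with the mean of all probes (adjusted p = 0.0509) and with median centring (adjusted p = 0.0667).

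Several organ lists were lower. Of 27 notochord and floor plate genes 15 fell and 4 rose, unchanged when adjusted over the list alone, with a median of -0.31. They included plod1a (-1.01), a collagen lysyl hydroxylase, and the axial regulators tbxta (-0.61), noto (-0.56) and shhb (-0.55). Of 25 otic vesicle and lateral line genes 14 fell and 1, pax5 (0.68), rose, with 15 falls adjusted over the list alone and a median of -0.31. The probes of oc90 (-0.66 and 1.14) and of eya1 (-0.53 and 0.31) opposed each other, while all 4 probes of pax2a were below 0 (brightest -0.64). Of 26 pronephros genes 12 fell and 3 rose, unchanged when adjusted over the list alone, with a median of -0.24. The cilium regulator foxj1b (-0.96) and the nephrin gene nphs1 (-0.61) were among the falls. Of 25 myogenic regulators 9 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of -0.21, among them prdm1a (-0.90), fgfr4 (-0.61, second probe -0.11) and myf5 (-0.57). The adjusted p was 0.0312 for notochord, 0.0196 for otic, 0.0271 for pronephros and 0.0378 for myogenic genes. With an estimated correlation the adjusted p was 0.497, and 0.501 for pronephros.

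These organ calls were near the threshold. The notochord call ended without replicate 2 (adjusted p = 0.0555), without replicate 3 (adjusted p = 0.0841) and with median centring (adjusted p = 0.179). The otic call ended without replicate 1 (adjusted p = 0.0612), with the mean of all probes (adjusted p = 0.0562) and with median centring (adjusted p = 0.121). For pronephros it ended without replicate 1 (adjusted p = 0.0792), without replicate 2 (adjusted p = 0.0545) and with median centring (adjusted p = 0.0928). For myogenic regulators it ended without replicate 1 (adjusted p = 0.113), without replicate 2 (adjusted p = 0.0796) and with median centring (adjusted p = 0.233).

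Germ plasm and maternal transcripts were lower, with falls in 12 of 24 genes against 3 rises (13 and 3 adjusted over the list alone), with a median of -0.26. The adjusted p was 0.0286, or adjusted p = 0.593 with an estimated correlation, and the call ended without replicate 1 (adjusted p = 0.193) and with median centring (adjusted p = 0.121). Falls included gdf3 (-0.90) and the egg envelope genes zp2.1 (-0.66) and zp2.2 (-0.56), and ca15b (0.56) rose.

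Genes of the proteasome, the respiratory chain and the cytosolic ribosome were higher as lists, by small amounts that differed between members and arrays. Of 41 proteasome genes 23 rose and none fell (24 adjusted over the list alone), with a median of 0.30 and adjusted p = 7.3e-05, or adjusted p = 0.497 with an estimated correlation. The immunoproteasome subunit gene psmb9a (0.88, SE 0.08), psmd10 (0.67), psmd13 (0.55) and psma6l (0.48) led it. Of 57 respiratory chain genes 29 rose and 4 fell (31 and 4 adjusted over the list alone), with a median of 0.30 and adjusted p = 7.6e-05, or adjusted p = 0.497 with an estimated correlation. The ATP synthase gene atp5pf (1.11) and the complex I gene ndufa1 (1.24) rose, while the cytochrome oxidase gene cox6a2 fell by 1.12. Of 24 ribosomal protein genes 7 rose and none fell (6 adjusted over the list alone), with a median of 0.27 and adjusted p = 5.7e-04, or adjusted p = 0.497 with an estimated correlation. After rpl36 (2.48), rises included rpl22l1 (1.14) and rpl31 (0.74, second probe 1.49), and 17 members did not pass. The list medians within slide 1 and within slide 2 were 0.22 and 0.29 for the proteasome, 0.40 and 0.25 for the respiratory chain, and 0.55 and 0.19 for the ribosome. The ribosomal median on the dye-swapped replicate 3 alone was 0.09.

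Cell cycle genes were higher in 26 of 92 cases and lower in 9, unchanged when adjusted over the list alone, with a median of 0.16 and adjusted p = 0.0147, or adjusted p = 0.497 with an estimated correlation. The rises included cks1b (0.73) and the checkpoint kinase gene chek2 (0.59), and the condensin gene ncapd3 fell (-0.83). The probes of another condensin gene, ncaph, opposed each other (1.04 and -0.48). This call ended without replicate 1 (adjusted p = 0.122) and with median centring (adjusted p = 0.0619). In the list of heat shock and unfolded protein response genes, 19 of 57 rose and 8 fell (21 and 8 adjusted over the list alone), with a median of 0.12 and adjusted p = 0.0474, or adjusted p = 0.497 with an estimated correlation. The chaperone genes hsp90aa1.2 (1.29) and dnaja1 (1.07) and the stress gene ddit4 (1.37) rose. The phosphatase regulator gene ppp1r15a, which acts in the recovery from translational arrest, fell by 1.90. This call ended with any replicate left out (adjusted p = 0.0895, 0.0555 and 0.103 without replicates 1, 2 and 3) and with 6 of the other settings (adjusted p between 0.0506 and 0.114).

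**Figure D3:**
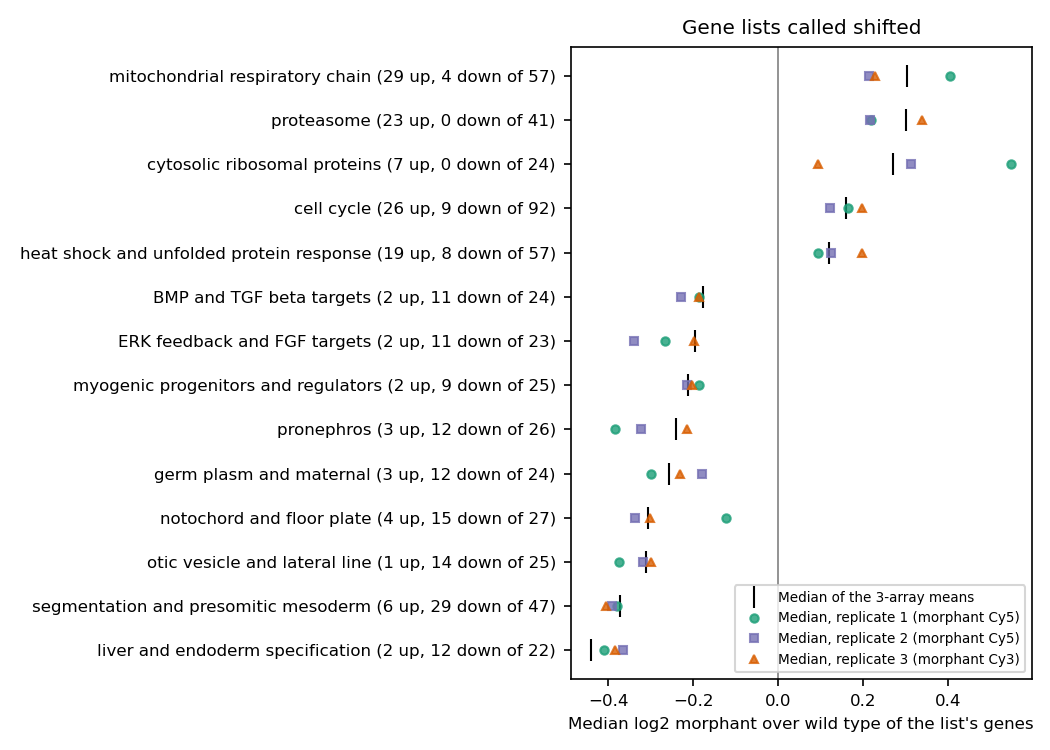
Median log2 ratio of morphant over wild type (x axis) of 14 of the gene lists called with the preset correlation (y axis, with the numbers of genes higher, lower and measured), shown per array as points and over the array means as a bar. The medians of all 3 arrays lie on the same side of 0 for every list shown, from -0.44 for liver and endoderm specification to 0.30 for the respiratory chain.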

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

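Camera on ranks and camera without the genes that have called probes of opposite sign were chosen after seeing the data. Named genes past the threshold kept their direction in each setting in which they were tested, and the number of calls changed. With the filter on both channels only 180 of 188 named genes were tested, and eef2a.1, ppt2a.1, hpdb, cyp2aa7 and mxc were among those left out. Over the named genes and their alternatives, 2461 of 2624 results kept direction and side of the threshold, 158 kept direction only, 127 of these with median centring, and 5 changed sign. The sign changes were all of genes that did not pass in the main analysis. They were tnfrsf1a (0.0252) and epha2a (0.0164) with median centring, and sort1a with a dye term (-0.0403), without replicate 1 (-0.0222) and without replicate 2 (-0.0583), against 0.0994 without replicate 3. Median centring in place of loess left 715 probes, 409 higher and 306 lower, all at least 2-fold, called 6 lists, moved the median of all probes to 0.10, turned the sign of 2 of the 9435 called probes, gave grna 0.46 and grnb 0.74 with neither past the threshold, and lowered the lowest correlation between arrays to 0.482. The cause was not tested. Agilent's own log ratio, and the series' value table, which holds the same values, called 2160 probes at 2-fold or more against 971. Without a filter on dim probes the lowest correlation was 0.777 against 0.818. With an estimated correlation limma's camera called 0 lists, with 1 at an unadjusted p under 0.05 and 33 by fry. Leaving out a replicate gave 6187 to 8233 probes, 2775 to 3875 of them higher and 3412 to 4358 lower, 887 to 1121 at 2-fold or more, and 10 to 12 lists, with 1 residual degree of freedom in place of 2. The same fits gave grna 0.26 to 0.36, grna.2 0.02 to 0.12 and grnb 0.39 to 0.70. A slide block could not be estimated by duplicateCorrelation from 3 arrays and was not run. The ratio within each array already pairs morphant with wild type, so no further replicate block was fitted. Camera on ranks and camera without those 63 genes each called 15 lists, the same 15. Signal over background limits the changes of dim probes, which the offset shrinks. Turning the sign of 1 array, in each of 3 ways, gave 0 called probes in limma against 9435 (41 to 116 at an unadjusted p under 0.05), and at most 6 called lists against 15. With 4 patterns of sign, of which 1 gave as many, the share cannot go below the 0.05 threshold.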

Other observations

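The test on other probes of genes with a 4-fold change, the dye and stage tests of the presomitic genes, and the within-slide test were chosen only after the result was seen. Several groups that were not called as lists held called changes in both directions, some of them large. Over all 9227 named genes 41.3% passed, so counts near that share do not set a group apart. Among 44 genes of innate immunity and interferon, 17 rose and 12 fell, unchanged when adjusted over the list alone (adjusted p = 0.194, or adjusted p = 0.622 with an estimated correlation). The cytokine gene tnfb rose by 1.57 (SE 0.09), the interferon-induced gene mxc by 1.79 (SE 0.11, second probe 0.83, with wild-type signal well above background on 1 of 3 arrays) and stat3 by 1.23 (SE 0.08, other probes 0.53 and 0.38). Of 28 macrophage and neutrophil markers 5 rose and 7 fell, or 6 and 7 adjusted over the list alone (adjusted p = 0.998), with mmp9 at 0.93 and tyrobp at -0.97. Of 73 lysosome genes, a group of interest for granulins, 12 rose and 14 fell, or 11 and 14 adjusted over the list alone (adjusted p = 0.845). Against the rise of ctsba (4.60), the ceramidase gene asah1a fell by 1.14. Of 34 blood vessel genes 2 rose and 11 fell, unchanged when adjusted over the list alone (adjusted p = 0.229), among them flt4 (-1.26), a receptor for vascular growth factors, and cldn5a (-1.57). Of 39 apoptosis genes 9 rose and 14 fell, or 10 and 16 adjusted over the list alone (adjusted p = 0.292), with mcl1b at -1.54, casp8 at -1.40 and casp2 at 0.72.

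Glycolysis genes and their hypoxia-related companions fell in 11 of 25 cases and rose in 3, or 11 and 5 adjusted over the list alone (adjusted p = 0.194, or adjusted p = 0.497 with an estimated correlation), led by egln3 (-3.46) and pdk2b (-1.20), while gpib rose (0.80). In the eye, where 11 of 43 genes rose and 13 fell, unchanged when adjusted over the list alone (adjusted p = 0.896), the early field genes six7 (-1.99, second probe -0.55) and rx3 (-1.45) fell and the lens crystallin genes cryba1b (0.95) and crygn2 (0.83) rose. Among 17 hormone and pituitary genes 2 rose and 4 fell, or 2 and 3 adjusted over the list alone (adjusted p = 0.897), and the median (-0.08) and mean (0.13) differed in sign. There gnrh2 rose by 1.97 (second probe 1.46) and the steroid hydroxylase gene cyp17a1 by 1.54 (other probes 1.09 and 0.91). In the skin, where 6 of 38 genes rose and 10 fell, or 7 and 10 adjusted over the list alone (adjusted p = 0.645), anxa2b rose by 2.13 and the E-cadherin gene cdh1 fell by 1.32. Contractile muscle genes rose in 20 of 47 cases and fell in 10, or 24 and 10 adjusted over the list alone (adjusted p = 0.110, or adjusted p = 0.497 with an estimated correlation), with opposing probes for acta1b (0.77 and -0.41) and cavin4b (0.88 and -0.72). Neuronal genes rose in 10 of 62 cases and fell in 8, or 9 and 8 adjusted over the list alone (adjusted p = 0.549).

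Probes of the same gene sometimes moved in opposite directions. The widest gap among bright probes was in ctcf, which encodes a chromatin insulator protein (-2.20 and 1.04), singled out after its values were seen. Noise in dim probes is argued against, since 8.31% of 337 pairs of called bright probes had opposite signs (95% interval 5.59% to 11.8%). Dye bias is argued against as well, because 100% of 31 bright pairs whose means over replicates 1 and 2 had opposite signs, at least 1 apart on the log2 scale, kept their order on the dye-swapped array. A difference in transcript form or sequence between the pools may contribute, but it stays open. Of the other probes of genes with a 4-fold change, 53.3% showed less than 0.5 of that change on the log2 scale (95% interval 26.6% to 78.7%, 15 probes). The share was 55.9% of 127 probes for 2- to 4-fold changes and 49.1% of 1196 probes for smaller ones. The other probe is always the dimmer one, and the offset pulls dim ratios toward 0, so this share cannot decide the question. Probe sequences and mistaken probe names were not tested.

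The presomitic and endoderm lists were lower in morphants. Dye bias is argued against, since the presomitic list had a median of -0.40 on the dye-swapped array (95% interval -0.55 to -0.26). Array normalization is argued against for the presomitic list, since its median nearest to 0 under Agilent's log ratio or median centring was -0.25 (95% interval -0.41 to -0.11). The endoderm list was not tested in this way. This interval and the one before it resample genes as if they were independent. A difference in developmental stage, with morphant pools older than the wild-type pools, could raise late markers, and 67 of these, written after the list results were known, had a median of 0.27 (camera p = 9.7e-05, or p = 0.0802 with an estimated correlation), with 15 higher and 2 lower of 23 sarcomere genes, 6 and 0 of 8 pigment, 5 and 3 of 9 globin and haem, 7 and 3 of 15 lens, and 4 and 1 of 12 neuron genes. None of the lists of muscle, pigment, erythroid, eye or neuron genes written before was called (adjusted p = 0.110, 0.655, 0.740, 0.896 and 0.549), and staging of the pools is not given in the sources used here, so an effect of the knockdown, of injection, and of age at collection all stay open. The other lists that were lower, such as those of organs and signalling targets, were not tested for a stage difference. Age at collection stays open for them too.

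The proteasome and respiratory chain lists were higher in morphants, with 18 of 41 and 24 of 57 members not past the threshold. Intensity-dependent normalization is argued against, since both medians (0.30 and 0.30) lay above the central 95% of the medians of 10000 random lists matched on intensity, whose upper end was at most 0.11. For the ribosomal list (0.27) that margin was narrow, since its matched lists had a median of 0.10 and an upper end of 0.24. A single slide is argued against, since the lowest median of the proteasome and respiratory chain lists within a slide was 0.22. A biological difference between injected and uninjected embryos stays a hypothesis. These arrays cannot separate injection itself from a knockdown of granulin A, as no control morpholino was analysed here and the arrays do not measure protein.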
